A study of Mus musculus with 7 samples.

How the data were processed

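PBMCs of mice at week 8 of serial blood collection gave 7 libraries, 1 for each of 7 groups (Non, and FV, RP and TV each without and with ibuprofen). Per the labels' protocols, total RNA was purified with an RNeasy kit and each library was made from it with a stranded mRNA kit. Per the submitters' processing notes, Trimmomatic 0.38 and HISAT2 2.1.0 were used with the mouse build mm10, without stated roles. The program that counted reads, the annotation release, the use of strand and any pooling of animals are not given in the sources used here. The deposited table held 45777 genes with, per library, 3 kinds of value made by the authors. Its read counts per gene, as deposited, were whole numbers that the authors had not normalized, per the file headers and the values. Its FPKM values, per kilobase of transcript and sequencing depth, were deposited by the authors and not used in any test. Its TPM values, scaled for transcript length, were deposited by the authors and sum to the same total in each library; they were used only as an alternative scale. Columns were matched to samples by the library number in the labels. Gene IDs were matched to a GRCm38.p6 gene table, which is the same assembly as mm10, for 45679 of the genes, and coordinates are 1-based.

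A stranded mRNA kit selects transcripts with a poly(A) tail, so globin mRNA from red cells is kept, and the share it takes lowers every other gene on a TPM scale. Counts were therefore scaled with TMM (trimmed mean of M values), and given as CPM, counts scaled to a common library size, with factors that ran from 0.553 in TV without ibuprofen to 1.31 in FV with ibuprofen. A count of 3 was taken as the floor, which equals 0.0383 to 0.0916 CPM. A chi-square comparison of the 21 pairs of libraries, with a lowest value of 30.7 per degree of freedom, found no pair closer than sampling noise, so no library was treated as a repeat of another.

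Computation used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Ibuprofen and the 3 differences between routes were tested in the 6 collected libraries with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) on the deposited counts, with route and ibuprofen as additive terms and 2 residual degrees of freedom, over genes with a mean of at least 1 CPM. The residual is then the difference of the ibuprofen effect between routes, so that difference itself could not be tested. Collection without ibuprofen was compared with Non in all 7 libraries, where Non was fitted exactly and assumed to vary like the others. The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and a standard error is the log2 fold divided by the square root of the F statistic. Pairs of libraries were compared without a test, as genes at least 2-fold apart (log2 CPM with a prior count of 2) with a mean of at least 10 CPM.

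Before the data were examined, 28 gene lists (749 genes, 2 of which were not in the table used) were fixed for blood cell types, for tissues at the collection sites and for pathways, together with the tests, the alternatives and the rule for named genes. The lists covered erythroid, platelet, neutrophil, classical and nonclassical monocyte, B cell, plasma cell, T cell, regulatory T cell, NK and cytotoxic, dendritic, basophil with mast cell and eosinophil, skin and hair, skeletal muscle, endothelial and stromal, and gland markers. The pathway lists were inflammatory cytokines with NF-kB targets, prostaglandin and leukotriene, type I interferon, immediate-early, glucocorticoid, heat shock with unfolded protein, hypoxia with glycolysis, cell cycle, MHC class II, ribosomal protein and oxidative phosphorylation, and a sex chromosome list was given as values only. The inflammatory list shares 7 genes with other lists and the glucocorticoid list 5. Of the neutrophil list, 25 of 30 genes passed the filter, and of the endothelial list 5 of 20. The 24 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. A list's median between a pair of libraries was set against 10000 random lists matched on expression in 20 bins, for 216 such medians. List means with ibuprofen and the distance from Non used an exact 2-sided sign-flip permutation over 3 routes.

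Named genes were chosen by a rule. For a tested comparison these were the 12 largest folds per direction among genes that passed, and where fewer than 5 passed, the 5 with the smallest p, all at a mean of at least 5 CPM and, for ibuprofen and for Non, with the same direction in all 3 routes; for pairs of libraries, the 6 largest folds per direction; and from each list the 4 members with the highest mean CPM, with Ptgs1 and Ptgs2 always. Predicted genes, clones, pseudogenes and single receptor segments were left out of the rule. Ccr2, the genes of the last part and the tissue genes named below the filter (Krt7, Scd3, Aqp5, Dmkn, Krt10 and Tnnt3) were chosen after their values were seen.

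The pipeline was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For ibuprofen over 11774 genes it recovered 85% and 100% of them, for RP minus FV over 11774 genes 68% and 100%, and for collection against Non over 11804 genes 34% and 98%. False calls were 8 of 214, 10 of 192 and 12 of 152 in the same order. A shifted list was found each time, with 0 other lists called. The simulated genes varied independently and had no other differences between libraries, so these rates do not cover lists whose genes vary together. Each simulated gene also took the variation that the fitted trend gives at its level, with no scatter of its own. The recovery rates therefore do not cover real genes that vary more than the trend, and do not show what these libraries could detect. The alternatives were DESeq2 size factors, no filter or a mean of at least 5 CPM, the erythroid list left out, other prior counts, the TPM scale, DESeq2, limma-voom, the legacy edgeR form, other model terms and leaving out each library in turn.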

Results

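Gene expression was measured by RNA sequencing of peripheral blood mononuclear cells (PBMCs), the lymphocytes and monocytes separated from blood, in mice at week 8 of serial collection. The labels give 7 groups with 1 library each. They are a control named Non and 3 collection routes, the facial vein (FV), the retro-orbital plexus behind the eye (RP) and the tail vein (TV), each without and with ibuprofen, an inhibitor of the cyclooxygenases encoded by Ptgs1 and Ptgs2. The title names pain and inflammation as the subject, so the comparisons ask how the blood transcriptome differed by collection, by route and by ibuprofen. Total counts ranged from 47903611 in FV without ibuprofen to 63801032 in RP without ibuprofen. No group had a replicate, and the sources used here do not say whether a library pooled several animals, so every p-value measures only the spread between these libraries, which may be technical.

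Adult globin transcripts (Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, the hemoglobin chains of red cells) took 58.4% of all counts in Non. Their share was 53.4% and 46.3% in FV without and with ibuprofen, 54.0% and 62.4% in RP, and 70.9% and 64.6% in TV. The 95% Wilson interval of each share was at most 0.1 percentage points wide. The whole erythroid list took between 48.7% of counts in FV with ibuprofen and 74.3% in TV without ibuprofen. Mitochondrial ribosomal RNA made up 1.03% of the counts outside the erythroid list in Non, 2.68% and 2.08% in FV without and with ibuprofen, 1.35% and 1.06% in RP, and 3.07% and 1.67% in TV. At 10 CPM, the count of a gene scaled to library size, the library with the smallest effective size held 327 counts, with an exact Poisson interval of 293 to 364. Such intervals cover counting error only. All 7 libraries held the Y-linked transcript Ddx3y, between 21.4 and 66.9 CPM before scaling, and at most 0.0784 CPM of Xist. Markers of skin, skeletal muscle and the glands near the eye gave no testable group, since 1 member of each list passed the expression filter. These were Sfn at 1.22 to 3.81 CPM, Neb at 0.903 to 3.55 CPM and Slc12a2, which is also on the nonclassical monocyte list, at 10.8 to 22.9 CPM. Below the filter, some members, such as Krt7, Scd3, Aqp5 and Dmkn, held most of their few counts in the FV libraries. Others, such as Krt10 and Tnnt3, did not. Between FV without and with ibuprofen, Dmkn had 213 and 12 counts, while Krt7 had 143 and 117, Scd3 109 and 72, and Aqp5 30 and 31. The filter thus does not show that such tissue was absent.

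Against Non, neutrophil, platelet and classical monocyte transcripts were higher, and B and T cell transcripts lower, in FV without ibuprofen and TV without ibuprofen. The median log2 fold of the 25 neutrophil genes was 1.98 in FV and 1.15 in TV without ibuprofen, against 0.09 in RP. For the 29 platelet genes the medians were 1.16 in FV, 0.36 in RP and 2.12 in TV, and for the 24 classical monocyte genes 1.02, -0.01 and 0.93. B cell genes lay at -1.32 in FV, 0.26 in RP and -0.58 in TV, and T cell genes at -0.83, -0.36 and -1.05. Erythroid genes lay at -0.45 in FV and -0.27 in RP without ibuprofen and at 1.14 in TV. Among the neutrophil genes, S100a8, a subunit of calprotectin, stood at 241 CPM in FV without ibuprofen against 17.5 CPM in Non, and the metalloproteinase Mmp8 at 248 against 21.4 CPM. The acute-phase gene Saa3 (gene ID 20210; mm10 chromosome 7, 46711998 to 46719615) reached 256 CPM in FV without ibuprofen and 17.4 CPM in TV without ibuprofen, against 0.697 CPM in Non and 0.676 CPM in RP without ibuprofen.

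In the libraries with ibuprofen, the neutrophil medians against Non were 0.94 in FV, 0.40 in RP and -0.15 in TV. Platelet medians were 1.68, -0.33 and 0.63, classical monocyte medians 0.82, -0.42 and -0.04, B cell medians -0.61, 0.23 and -0.03, and T cell medians -0.30, 0.18 and 0.08. Nonclassical monocyte genes, the patrolling subset that depends on Nr4a1, stayed between -0.15 and 0.46 in all 6 libraries. Prostaglandin and leukotriene pathway genes lay at 0.63 in FV, -0.01 in RP and 0.78 in TV without ibuprofen, and at 0.56, -0.18 and 0.04 with it. Inflammatory cytokine and NF-kB target genes lay at 0.48 in both FV and TV without ibuprofen and between -0.08 and 0.10 in the other 4 libraries. Among 10000 random lists of the same size and expression, the neutrophil, platelet and classical monocyte medians of FV without, FV with and TV without ibuprofen were all at percentile 100, and the B and T cell medians of those libraries at percentile 0.

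**Figure D1:**
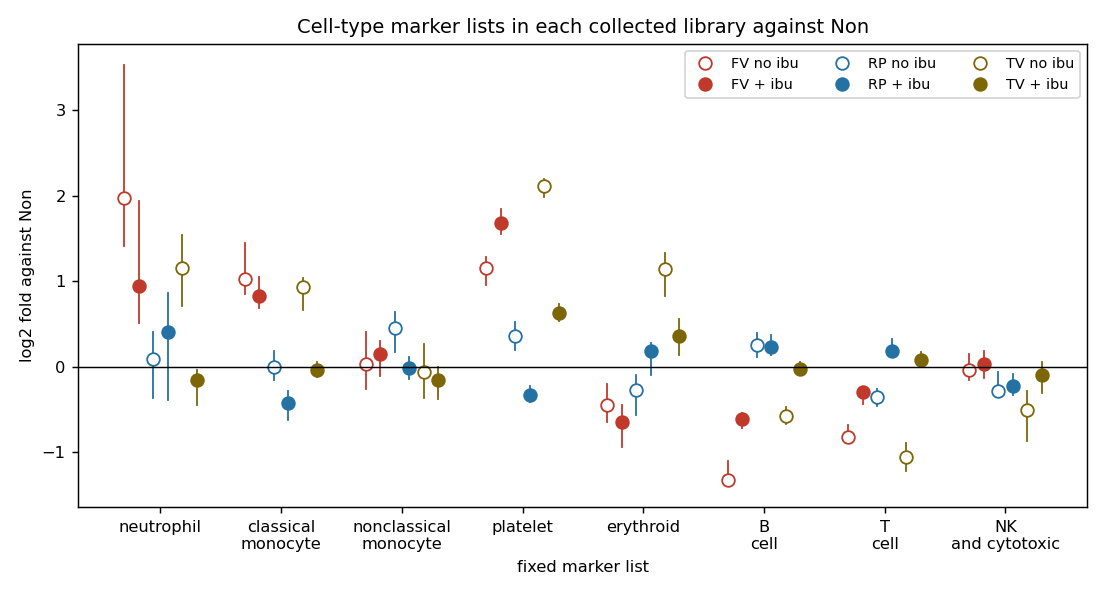
Median log2 fold against Non (vertical axis) of 8 cell-type marker lists (horizontal axis) in the 6 collected libraries; open circles are libraries without ibuprofen, filled circles with ibuprofen, and lines span the middle quartiles of the genes on a list. The neutrophil medians reach 1.98 in FV and 1.15 in TV without ibuprofen, and the B cell median falls to -1.32 in FV without ibuprofen.

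The number of genes at least 2-fold from Non, with a mean of at least 10 CPM, was 473 in FV without ibuprofen (370 higher, 103 lower) and 660 in TV without ibuprofen (581 higher, 79 lower). It was 25 in RP without ibuprofen (13 higher, 12 lower). With ibuprofen it was 342 in FV (320 higher, 22 lower), 20 in RP (9 higher, 11 lower) and 32 in TV (24 higher, 8 lower). In FV without ibuprofen the largest increases after Saa3 (log2 fold 8.45) were Il1r2, the decoy interleukin-1 receptor, at 5.96, the iron-binding Lcn2 at 4.98, Pcp4l1 at 4.36, Lrg1 at 4.23 and S100a8 at 3.78. The largest decreases there were Hbq1a at -4.01, the B cell chemokine receptor Cxcr5 at -1.88, Phospho1 at -1.80, Cacna1i at -1.75, the immunoglobulin D gene Ighd at -1.69 and Als2cl at -1.57. In FV with ibuprofen the largest were Pcp4l1 at 5.67, Ngp at 2.79, Mest at 2.45, Myct1 at 2.33, the platelet gene Treml1 at 2.32 and Slamf1 at 2.13, and the lowest Cwc22 at -1.80, Ly6d at -1.65 and Dusp2 at -1.36.

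In RP without ibuprofen the largest were Cd99l2 at 2.89, Adamdec1 at 2.30 and Aak1 at 1.66, and the lowest Hbq1a at -2.95, Rpl29 at -2.87 and Ybx3 at -1.61. RP with ibuprofen had Pcp4l1 at 4.40, Aak1 at 1.59, Mmp9 at 1.12 and the cytokine Il1b at 1.01, with Vcan at -1.83, Adamdec1 at -1.57 and Chil3 at -1.53 lowest. TV without ibuprofen had Pcp4l1 at 6.5, Mtss2 at 2.97, Map1a at 2.77 and the platelet protein multimerin, Mmrn1, at 2.53. Its lowest were Ccdc6 at -2.55, Hbb-bh1 at -1.48, Hbb-y at -1.45 and the T cell genes Cd8b1 at -1.42, Themis at -1.40 and Zap70 at -1.39. TV with ibuprofen had Pcp4l1 at 5.05, LOC115487803 at 1.64 and Cd93 at 1.56, with Rpl29 at -2.53, Cwc22 at -2.00 and Rpl35a at -1.18 lowest. Hbq1a, Rpl29, Rpl35a, Cwc22, Lilrb4a and the embryonic globins share sequence with near-identical copies or pseudogenes, so their counts are uncertain.

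These comparisons set 1 library against another and have no replicate check. On the deposited TPM scale, where the globin share enters every value, the same limit of 10 leaves 1850 to 3045 genes, against 6051 to 6175 by CPM, so scale and gene set change together. The median log2 fold of those genes was 0.23 and 0.50 in FV without and with ibuprofen, 0.19 and -0.20 in RP and -0.90 and -0.42 in TV. The split in that set was 293 higher and 28 lower in FV without ibuprofen, 14 higher and 796 lower in TV without ibuprofen, 2 higher and 13 lower in RP with ibuprofen, and 2 higher and 14 lower in TV with ibuprofen; in FV with ibuprofen it was 484 higher and 6 lower. Leaving the erythroid list out gave 14 higher and 36 lower in RP with ibuprofen, 418 higher and 65 lower in FV with ibuprofen, 555 higher and 170 lower in FV without ibuprofen, and 702 higher and 172 lower in TV without ibuprofen.

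Across the 3 routes without ibuprofen, platelet, neutrophil and classical monocyte genes were higher than in Non and T and B cell genes lower in the fit of all 7 libraries. All 29 platelet genes were higher, with a mean log2 fold of 1.26, as were 23 of 25 neutrophil genes (1.20) and 23 of 24 classical monocyte genes (0.72). All 30 T cell genes were lower (-0.71), as were 27 of 28 B cell genes (-0.48). The T cell transcription factor Tcf7 stood at -0.78 (standard error 0.26) and the homing receptor Ccr7 at -0.77 (standard error 0.19), while S100a9 was at 1.64 (standard error 0.57) and the platelet integrin Itga2b at 1.21 (standard error 0.56). None of these genes passed the test over all genes. In RP the fitted average did not hold, since B cell genes were higher than in Non (median 0.26, 25 of 28 higher), classical monocyte genes were at -0.01 (12 of 24 higher) and neutrophil genes, at 0.09, were inside the random range.

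Among the genes that the naming rule admits, the smallest p-values went to Thbs1, the adhesive protein thrombospondin 1 (chromosome 2, 118111876 to 118127133), at 1.69 (standard error 0.291), Aak1 at 1.20, the chitinase-like myeloid gene Chil3 (chromosome 3, 106147554 to 106167564) at 1.79 (standard error 0.335), the leukotriene-cleaving dipeptidase Dpep2 at 1.32 and the myeloid receptor Cd33 at 1.60. On the lower side stood Als2cl at -0.96, Amigo2 at -1.11, the interferon-inducible GTPase Tgtp1 at -0.86, Atp9a at -1.19 and Cd4, the coreceptor of helper T cells (chromosome 6, 124864693 to 124888247), at -0.82 (standard error 0.171). Each of these 10 had an adjusted p of 0.623. Ptgs1 stood at 1.12 (standard error 0.49) and Ptgs2 at 1.24 (standard error 0.58), both also at an adjusted p of 0.623.

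With edgeR, 0 of 11804 genes passed an adjusted p of 0.05 in this comparison, against 906 at an unadjusted p under 0.05, where chance gives about 590. That excess depended on the model. In the fit of 4 libraries with routes as replicates the number was 145, and with Non set against all 6 collected libraries 61, both below chance. The smallest adjusted p was 0.0749, for a predicted gene that the naming rule leaves out. DESeq2 called 17 genes, limma-voom 1 and the legacy form of the edgeR test 1. Adjusted over the list alone, 26 T cell, 2 platelet and 4 basophil, mast cell and eosinophil genes passed, with 1 classical monocyte and 1 prostaglandin gene, against 0 over all genes. By camera, 14 of 24 lists passed. The adjusted p was 2.33e-26 for T cells, 1.57e-17 for platelets, 4.81e-13 for neutrophils, 6.78e-13 for classical monocytes, 8.62e-12 for B cells and 9.42e-05 for ribosomal proteins (mean -0.21), all at an adjusted p of 0.614 with an estimated correlation. Other called differences were those of inflammatory (0.35), prostaglandin (0.42), heat shock (0.31), hypoxia (0.31), NK and cytotoxic (-0.24), basophil (-0.31) and MHC class II genes (-0.24), also at an adjusted p of 0.614 with an estimated correlation, and of immediate-early genes (0.24), at an adjusted p of 0.647 with an estimated correlation. Non was fitted exactly and assumed to vary like the other libraries. The calls of inflammatory, immediate-early (0.11), heat shock (0.20), hypoxia and MHC class II genes (-0.11) ended without FV without ibuprofen, those of NK (-0.10) and prostaglandin genes (0.21) without TV without ibuprofen, and that of basophil genes without FV (-0.18) or RP without ibuprofen; the platelet mean was 0.78 without TV without ibuprofen. The basophil mean was -0.49 without TV without ibuprofen and the immediate-early mean 0.37 without RP without ibuprofen. With Non set against all 6 collected libraries the calls of basophil, immediate-early, heat shock and MHC class II genes ended, as did those of basophil and MHC class II genes in the fit of 4 libraries, those of basophil, prostaglandin and MHC class II genes with no filter, and those of basophil and heat shock genes at a mean of at least 5 CPM.

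Ibuprofen was compared over the 3 routes, each route holding its own pair of libraries. T cell genes were higher with ibuprofen, with all 30 members positive and a mean log2 difference of 0.71 ± 0.36 (SD over the 3 routes), and all 28 B cell genes were higher in the fit at 0.36 ± 0.31. In RP alone the B cell difference was 0.0063, with 16 of 28 genes higher. Classical monocyte genes were lower at -0.59 ± 0.27, with 23 of 24 members below 0. Neutrophil genes, at -0.69 ± 0.86, and platelet genes, at -0.53 ± 0.98, were lower on average and differed in sign between routes. Genes of the heat shock and unfolded protein response (-0.42 ± 0.29), immediate-early genes (-0.35 ± 0.26) and inflammatory cytokine and NF-kB target genes (-0.30 ± 0.26) were lower with ibuprofen on average. In RP these differences were near 0, at -0.092 for heat shock, -0.078 for immediate-early and -0.0080 for inflammatory genes. A change of these pathway lists, or of the ribosomal protein list, apart from the shares of cell types was not tested.

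The T cell genes with the highest mean CPM were Tcf7, Ccr7, Satb1 and the kinase Lck. Their log2 differences with ibuprofen were 0.77 (standard error 0.20), 0.76 (0.14), 0.56 (0.14) and 0.59 (0.19) in that order. Among classical monocyte genes, the fibronectin gene Fn1 stood at -0.89 (0.19), Chil3 at -1.37 (0.22), the lysozyme Lyz2 at -0.50 (0.31) and Mpeg1 at -0.56 (0.25). The immediate-early gene Fos stood at -0.81 (0.21), and Nr4a1 at -0.76 (0.14), with route values of -0.80, -0.73 and -0.71. Ptgs1 (chromosome 2, 36216742 to 36258593), the constitutive cyclooxygenase, stood at -0.52 (0.33), with 0.54 in FV, -0.86 in RP and -1.15 in TV. Ptgs2 (chromosome 1, 150100031 to 150108234), the inducible one, stood at -0.95 (0.39), with -1.18 in FV, 0.12 in RP and -1.75 in TV, at 1.17 to 4.75 CPM. The platelet list medians with ibuprofen, 0.59 in FV, -0.70 in RP and -1.46 in TV, had the signs and order of Ptgs1. A change of Ptgs1 apart from the share of platelets was not tested.

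By smallest p-value under the naming rule, the genes higher with ibuprofen were Xkrx at 0.95 (standard error 0.13), the T cell receptor adaptor Trat1 at 0.84, the potassium channel Kcnn4 at 0.92, the transcription factor Lef1 (chromosome 3, 131110297 to 131224357) at 0.89 and Cd4 at 0.72. The genes lower were Saa3 at -3.91 (standard error 0.451), the sphingomyelin synthase Sgms2 at -0.99, Dpep2 at -1.24, the RNA sensor Tlr8 at -0.84 and Laptm4b at -1.52. All 10 had an adjusted p of 0.374 and the same sign in every route. Saa3 was 256 CPM without and 12.6 CPM with ibuprofen in FV, 0.676 and 0.157 CPM in RP, and 17.4 and 0.858 CPM in TV. Chil3 was 1140 and 502 CPM in FV, 148 and 39.9 CPM in RP, and 359 and 180 CPM in TV.

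**Figure D2:**
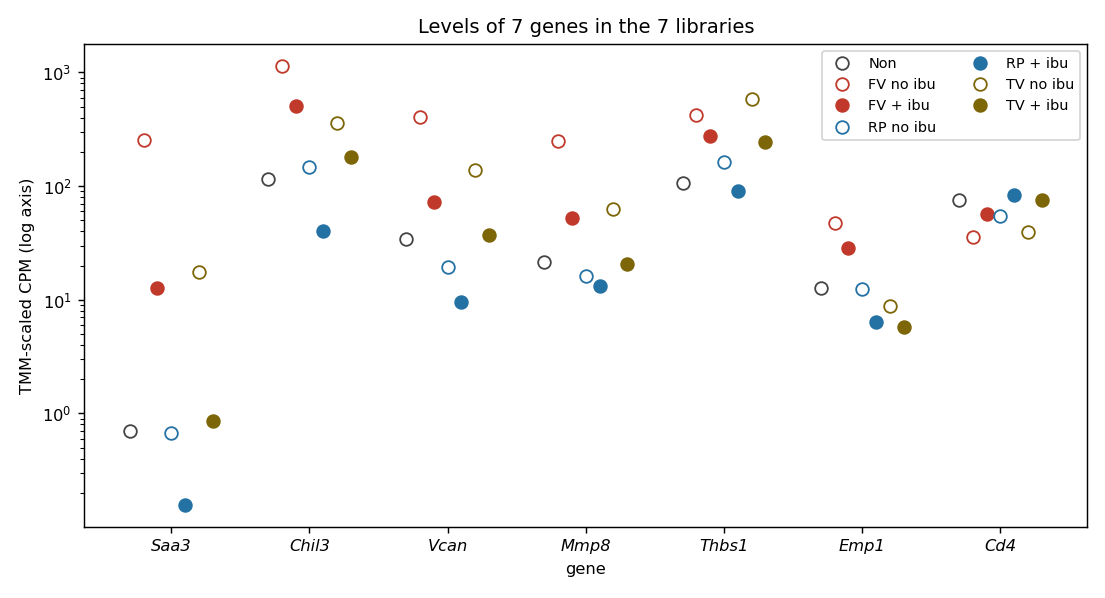
TMM-scaled CPM on a log axis (vertical) of 7 genes (horizontal) in the 7 libraries, with open circles for Non and libraries without ibuprofen and filled circles for libraries with ibuprofen. Saa3 stands at 256 CPM in FV and 17.4 CPM in TV without ibuprofen, and at 12.6 and 0.858 CPM with it.

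Of 11774 genes, 0 passed an adjusted p of 0.05 with edgeR, against 1244 at an unadjusted p under 0.05, 550 higher and 694 lower, where chance gives about 589. With no route term that number was 473, below chance. Without either TV library it was near what chance gives, so the excess rested on the TV pair. DESeq2 called 110 genes and limma-voom 1. Adjusted over the list alone, 28 T cell, 9 glucocorticoid response, 6 classical monocyte, 6 immediate-early and 2 basophil genes passed, with 1 nonclassical monocyte and 1 dendritic cell gene, against 0 over all genes. By camera, 18 of 24 lists passed. The adjusted p was 1.41e-38 for T cells, 9.91e-10 for B cells, 1.05e-08 for ribosomal proteins (mean 0.25, 48 of 49 members positive), 2.87e-15 for classical monocytes, 2.32e-09 for neutrophils, 4.93e-07 for platelets, 4.44e-07 for heat shock, 1.43e-07 for immediate-early and 7.55e-05 for inflammatory genes, each at an adjusted p of 0.601 with an estimated correlation. Also called, at an adjusted p of 0.601 with an estimated correlation, were regulatory T cell (0.24), NK and cytotoxic (0.16), nonclassical monocyte (-0.19), endothelial and stromal (-0.45), prostaglandin (-0.25), glucocorticoid response (-0.29) and hypoxia genes (-0.16). Dendritic cell genes (-0.35) stood at an adjusted p of 0.635 and erythroid genes (-0.16) at 0.832 with an estimated correlation. Plasma cell (0.08), basophil (0.13), interferon response (-0.09), cell cycle (-0.04), MHC class II (0.18) and oxidative phosphorylation genes (-0.04) were not called.

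An exact 2-sided sign-flip permutation over 3 routes cannot go below a p of 0.25, the value reached by 12 lists including T cells. The call for platelets ended without either TV library, with a mean of -0.11 or -0.08 in place of -0.54, as did those of regulatory T cell, NK (0.02 without TV with ibuprofen), endothelial (-0.12), prostaglandin (-0.05) and hypoxia genes (-0.07). The erythroid mean turned to 0.09 or 0.11 without a TV library and its call ended without either FV library, as did those of glucocorticoid (-0.12) and hypoxia genes. Those of nonclassical monocyte (-0.06 or -0.08), dendritic (-0.13 or -0.15) and endothelial genes ended without either RP library, and the dendritic call also without TV without ibuprofen. Without either FV library the mean was -1.06 for platelets and -0.63 for dendritic cells. The neutrophil call held without each library, with means from -1.19 without RP with ibuprofen to -0.40 without TV with ibuprofen, and the inflammatory mean was -0.46 without RP with ibuprofen and -0.19 without TV with ibuprofen. The immediate-early mean was -0.24 without FV without ibuprofen. Larger means were -0.45 and -0.47 for erythroid and -0.27 and -0.29 for hypoxia genes without RP without and with ibuprofen, -0.30 for nonclassical monocyte and -0.43 for prostaglandin genes without FV without ibuprofen, and -0.42 for prostaglandin and -0.74 for endothelial genes without FV with ibuprofen. The erythroid call also ended with DESeq2 size factors and at a mean of at least 5 CPM, those of dendritic and glucocorticoid genes at 5 CPM, that of regulatory T cell genes with no filter, and that of prostaglandin genes with no filter or no route term.

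**Figure D3:**
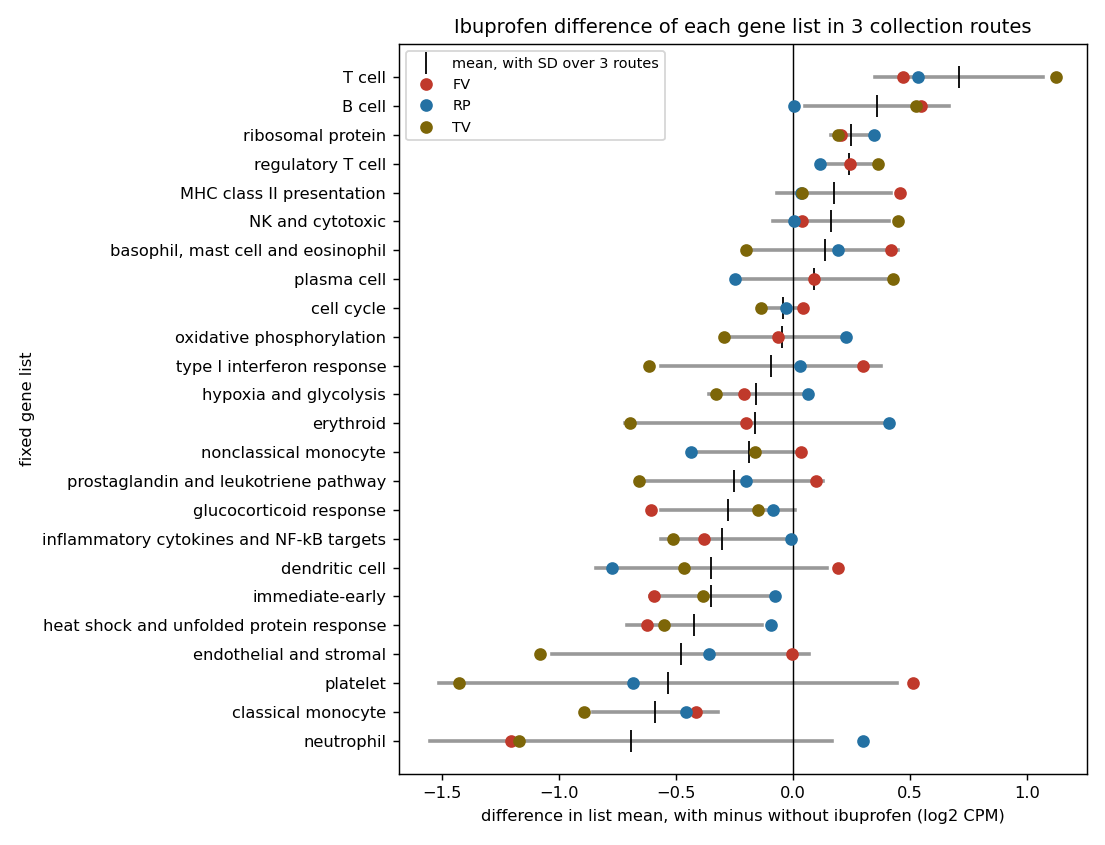
Difference in mean log2 CPM, with minus without ibuprofen (horizontal axis), of 24 gene lists (vertical axis) in FV, RP and TV; each point is 1 route, the black tick is the mean and the grey bar 1 SD over the 3 routes. T cell genes lie above 0 in all 3 routes (mean 0.71), while the neutrophil and platelet points lie on both sides of 0.

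Within routes, ibuprofen went with 118 genes at least 2-fold different in FV (32 higher, 86 lower), 54 in RP (21 higher, 33 lower) and 437 in TV (71 higher, 366 lower). In FV the acute-phase and myeloid genes Saa3 (-4.35), Il1r2 (-3.60), Lbp (-3.05), Lcn2 (-3.00), Vcan (-2.46) and Mmp8 (-2.26) were lowest, and Hbq1a (3.44), Adnp (1.72), Colec12 (1.70), Cxcr5 (1.47), Lrrn3 (1.46) and Slc39a4 (1.36) highest. In RP the lowest were Adamdec1 (-3.88), Cd99l2 (-2.71), Mest (-2.44), Peg10 (-2.11), Chil3 (-1.89) and Myof (-1.81), and the highest Pcp4l1 (3.77), Hbq1a (3.03), Rpl29 (2.55), Ybx3 (2.37), Pdk1 (1.93) and Cd93 (1.87). In TV the lowest were LOC105246914 (-2.12), Xaf1 (-2.02), S100a8 (-1.99), Lrg1 (-1.91), Vcan (-1.90) and Tgfb1i1 (-1.82), and the highest Ccdc6 (2.59), Hbb-bh1 (2.04), Hbb-y (2.00), the cytotoxic T cell coreceptor genes Cd8b1 (1.61) and Cd8a (1.53), and Hbb-bh2 (1.46). Vcan and Saa3 were the 2 genes at least 2-fold lower in all 3 routes, and 0 genes were at least 2-fold higher in all 3. Saa3 rested on 53 and 8 counts of its gene family in RP.

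Median log2 differences of T cell genes were 0.51 in FV, 0.57 in RP and 1.13 in TV, of B cell genes 0.59, 0.02 and 0.54, and of classical monocyte genes -0.21, -0.45 and -0.89. Those of neutrophil genes were -1.07, 0.25 and -1.17, of platelet genes 0.59, -0.70 and -1.46, and of erythroid genes -0.13, 0.45 and -0.73. Across 6153 genes, which are not independent replicates, the log2 difference with ibuprofen had a Pearson correlation of 0.0830 between FV and RP, 0.147 between FV and TV and 0.251 between RP and TV, with Spearman values of 0.0183, 0.202 and 0.334. The sign was shared by all 3 routes for 34.8% of genes, against 25% by chance. On the TPM scale, where the limit leaves 3240 genes in FV, 2483 in RP and 1484 in TV against 6239, 6050 and 6069 by CPM, the median log2 difference was 0.29, -0.39 and 0.39 and the splits were 76 higher and 27 lower, 10 higher and 90 lower, and 202 higher and 4 lower.

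The median absolute log2 fold from Non over 6141 genes was 0.291 and 0.240 in FV without and with ibuprofen, 0.131 and 0.108 in RP, and 0.335 and 0.10 in TV. The library with ibuprofen was nearer to Non in 3 of 3 routes, with a mean difference of -0.103 ± 0.115 (SD, n = 3 routes) and an exact 2-sided sign-flip permutation p of 0.25, the smallest that 3 routes allow. With the cell-type marker lists left out the 6 values were 0.284, 0.234, 0.128, 0.106, 0.324 and 0.0983. The markers were a small part of the 6141 genes, so these medians could hardly move and do not bear on the shares of cell types.

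**Figure D4:**
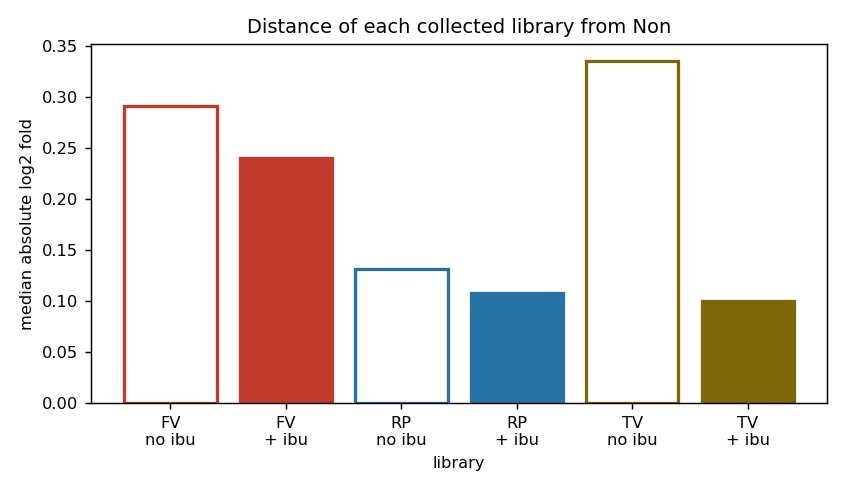
Median absolute log2 fold from Non (vertical axis) for the 6 collected libraries (horizontal axis), with open bars without and filled bars with ibuprofen. The bar with ibuprofen is the lower of the pair in each route, at 0.240 against 0.291 in FV and 0.10 against 0.335 in TV.

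Between RP and FV, B cell genes were higher in RP and neutrophil, platelet and classical monocyte genes lower. The 28 B cell genes had a mean log2 difference of 1.15, with 27 above 0, and included Ighm at 1.12 (standard error 0.24) and Cd79a at 1.31 (0.18). All 30 T cell genes were above 0, with a mean of 0.50. Neutrophil genes had a mean of -1.76, with S100a9 at -1.49 (0.47) and Mmp8 at -2.90 (0.49). All 29 platelet genes were lower (-1.49), as were all 24 classical monocyte genes (-1.31), including the chemokine receptor Ccr2 at -1.90 (0.29).

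Under the naming rule, the genes with the smallest p-values that were higher in RP included Siglecg, an inhibitory receptor of B cells (chromosome 7, 43408192 to 43418349), at 1.48 (standard error 0.155), Als2cl at 1.30, the BAFF receptor Tnfrsf13c at 1.37 and Akap2 at 1.31. The genes lower in RP were Emp1 (chromosome 6, 135362550 to 135383173) at -2.03 (standard error 0.156), Saa3 at -7.74, Chil3 at -3.27, Ms4a8a at -2.80 and Emilin1 at -1.52. All 9 had an adjusted p of 0.0740. With edgeR 0 of 11774 genes passed, against 2899 at an unadjusted p under 0.05 (1118 higher, 1781 lower), where chance gives about 589. The latter number was smaller without any 1 of the FV or RP libraries, and smallest without RP without ibuprofen, though still above chance. DESeq2 called 1076, limma-voom 48 and edgeR with the erythroid list left out 18.

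Adjusted over the list alone, 26 B cell, 27 platelet, 19 classical monocyte, 17 neutrophil, 11 prostaglandin, 8 glucocorticoid, 7 dendritic, 5 heat shock, 4 MHC class II, 3 T cell, 3 hypoxia, 3 endothelial, 2 NK, 2 basophil and 1 plasma cell gene passed, against 0 over all genes. By camera 11 of 24 lists passed, all at an adjusted p of 0.828 with an estimated correlation. Beside those above they were erythroid (0.46), MHC class II (0.44), plasma cell (-0.45), prostaglandin (-0.66), hypoxia (-0.45) and oxidative phosphorylation genes (-0.30). Regulatory T cell, interferon response, glucocorticoid and ribosomal protein genes, none called, differed in sign between median, mean and test, as in the glucocorticoid list with a median of 0.17 and a mean of -0.15. Without FV without ibuprofen 676 genes passed, without FV with ibuprofen 50, and without either TV library 1; the platelet mean was then -0.59 without FV with ibuprofen, the prostaglandin mean -0.35 without the same library, and the neutrophil mean -1.14 and -2.70 without RP without and with ibuprofen. The erythroid (0.02) and plasma cell (-0.19) calls ended without RP with ibuprofen, those of hypoxia (-0.29) and oxidative phosphorylation genes (-0.10) without RP without ibuprofen, and those of MHC class II (0.24), plasma cell and oxidative phosphorylation genes without FV without ibuprofen; the plasma cell call also ended without FV with ibuprofen. Larger means were 0.85 for erythroid and -0.72 for plasma cell genes without RP without ibuprofen, -0.48 for oxidative phosphorylation genes without RP with ibuprofen and 0.66 for MHC class II genes without FV with ibuprofen.

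Between TV and FV, erythroid genes were higher in TV, with all 41 members above 0 and a mean log2 difference of 1.25, in libraries whose globin shares were the highest of the 7. B cell genes were higher (0.60, 26 of 28) and neutrophil genes lower (-1.52, 24 of 25), as were classical monocyte genes (-0.60, 23 of 24). Cell cycle genes were higher (0.38, 25 of 35), with Ube2c at 1.42 (standard error 0.33) and Mki67 at 1.21 (0.20). Platelet genes, with a mean of -0.11, differed in opposite ways without and with ibuprofen, their medians against Non being 2.12 in TV and 1.16 in FV without it and 0.63 and 1.68 with it. The mean was -0.85 without FV without ibuprofen, 0.72 without FV with ibuprofen, -0.76 without TV without ibuprofen and 0.56 without TV with ibuprofen.

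Under the naming rule, the genes with the smallest p-values that were higher in TV were the amino acid transporter Slc38a5 at 1.98 (standard error 0.238), Cdkl1 at 1.67, the glycine transporter Slc6a9 at 1.39, cyclin A2, Ccna2, at 1.81 and Sh3yl1 at 1.5. Lower in TV were Emp1 at -2.32 (standard error 0.158; adjusted p 0.102), Saa3 at -3.81, Ms4a6d at -1.97, Gsto1 at -1.58 and Ms4a4a at -1.25, and the 9 other than Emp1 had an adjusted p of 0.294. With edgeR 0 of 11774 genes passed, against 1186 at an unadjusted p under 0.05 (622 higher, 564 lower). DESeq2 called 318 and limma-voom 7.

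Adjusted over the list alone, 29 erythroid, 15 neutrophil, 9 cell cycle, 8 B cell, 4 basophil, 2 classical monocyte and 1 heat shock gene passed, against 0 over all genes. By camera 11 of 24 lists passed. The adjusted p was 2.81e-50 for erythroid, 4.58e-24 for neutrophil and 6.93e-10 for classical monocyte genes, and with basophil (0.60), regulatory T cell (-0.36) and cell cycle genes these stood at an adjusted p of 0.497 with an estimated correlation. B cells (4.71e-18) stood at an adjusted p of 0.541, plasma cells (-0.37) at 0.669, NK genes (-0.34) at 0.695, nonclassical monocytes (-0.25) at 0.891 and interferon response genes (0.15) at 0.936 with an estimated correlation. Heat shock, ribosomal protein and oxidative phosphorylation genes, none called, differed in sign between median, mean and test. Without FV without ibuprofen 11 genes passed and without FV with ibuprofen 14; the calls of plasma cell (-0.12), regulatory T cell, NK (-0.12), nonclassical monocyte and interferon response genes (-0.25) ended without TV without ibuprofen, the nonclassical monocyte call also without FV with ibuprofen (-0.07), and the interferon call also without FV without ibuprofen (-0.11). The erythroid mean was 0.83 and the basophil mean 0.33 without TV without ibuprofen, and the classical monocyte mean -0.37 without TV with ibuprofen. Larger means were -0.65 for plasma cell, -0.56 for NK and 0.54 for interferon response genes without TV with ibuprofen, 0.47 for interferon response genes without FV with ibuprofen and -0.41 for nonclassical monocyte genes without FV without ibuprofen. The nonclassical monocyte and basophil calls also ended at a mean of at least 5 CPM.

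Between TV and RP, platelet genes were higher in TV, with all 29 above 0 and a mean log2 difference of 1.38, including Nrgn at 1.71 (standard error 0.51) and Itga2b at 1.5 (0.47). Erythroid (0.80, 40 of 41), classical monocyte (0.71, 22 of 24) and oxidative phosphorylation genes (0.38, 44 of 46) were higher in TV. All 28 B cell genes (-0.54) and all 30 T cell genes (-0.42) were lower. By smallest p-value under the naming rule, Thbs1 at 1.68 (standard error 0.238), the phospholipase Plcb1 at 1.28, LOC115487803 at 1.42, Saa3 at 3.93 and versican, Vcan (chromosome 13, 89655309 to 89743027), at 2.37 were higher in TV. Lower were Rpl35a at -0.86, the MHC class II gene H2-Eb1 at -1.19, the kinase Camk4 at -0.79, Rab11fip4 at -0.68 and Als2cl at -0.64, all 10 at an adjusted p of 0.381.

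With edgeR 0 of 11774 genes passed, against 1534 at an unadjusted p under 0.05 (1094 higher, 440 lower). The latter number fell below what chance gives without RP without ibuprofen or without TV without ibuprofen. It rose without TV with ibuprofen. DESeq2 called 189, giving 9359 genes no adjusted p, and limma-voom 0. Adjusted over the list alone, 23 platelet, 7 classical monocyte and 1 MHC class II gene passed, against 0 over all genes. By camera 16 of 24 lists passed, all at an adjusted p of 0.584 with an estimated correlation. They also held prostaglandin (0.52), basophil (0.49), cell cycle (0.38), heat shock (0.29) and hypoxia genes (0.27), which were higher, and nonclassical monocyte (-0.31), regulatory T cell (-0.29), MHC class II (-0.28), glucocorticoid (-0.23) and immediate-early genes (-0.20), which were lower. Plasma cell, inflammatory and ribosomal protein genes, none called, differed in sign between median, mean and test. Without FV without ibuprofen 5 genes passed and without FV with ibuprofen 32; the calls of nonclassical monocyte (-0.11), regulatory T cell (-0.19), hypoxia (0.11), heat shock (0.06) and MHC class II genes (-0.16) ended without RP without ibuprofen, those of heat shock, MHC class II and immediate-early genes without TV with ibuprofen, those of immediate-early (0.03) and glucocorticoid genes (-0.06) without RP with ibuprofen, and that of basophil genes (0.13) without TV without ibuprofen. Without TV without ibuprofen the means were 0.61 for platelets, 0.38 for erythroid, 0.47 for classical monocyte, -0.12 for T cell and 0.18 for prostaglandin and 0.19 for oxidative phosphorylation genes, and without RP without ibuprofen 0.38 for erythroid, -0.27 for B cell and 0.18 for oxidative phosphorylation genes; without RP with ibuprofen they were 1.24 for erythroid and 0.59 for oxidative phosphorylation genes, and without TV with ibuprofen -0.74 for T cell, 0.79 for prostaglandin and -0.18 for MHC class II genes. Without RP with ibuprofen the mean was -0.49 for nonclassical monocyte, 0.55 for heat shock and 0.45 for hypoxia genes. It was -0.39 for immediate-early and -0.36 for glucocorticoid genes without RP without ibuprofen, and -0.14 for glucocorticoid, 0.19 for heat shock and 0.14 for hypoxia genes without TV without ibuprofen. At a mean of at least 5 CPM the calls of cell cycle, heat shock and regulatory T cell genes also ended, and with no filter that of MHC class II genes.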

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

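The tests of lymphocyte share, of RNA without a poly(A) tail and of the marker share behind Saa3 and Chil3 were chosen only after the result was seen. In 9 cases the median of a gene list with ibuprofen lay above 0 and above the range of 95% of random lists in 1 route, and below 0 and below that range in another, and since each route holds 1 pair of libraries these differences were not tested. Lying outside that range was common, as for ibuprofen in FV, where 9 of 24 lists lay above it and 8 below. Erythroid genes differed by -0.576 between FV (-0.13) and RP (0.45) and by 1.18 between RP and TV (-0.73). Platelet genes differed by 1.29 between FV (0.59) and RP (-0.70) and by 2.05 between FV and TV (-1.46). Neutrophil genes differed by -1.32 between FV (-1.07) and RP (0.25) and by 1.42 between RP and TV (-1.17). Nonclassical monocyte genes differed by 0.568 between FV (0.21) and RP (-0.36). Type I interferon response genes differed by 0.733 between FV (0.20) and TV (-0.53). Oxidative phosphorylation genes differed by 0.510 between RP (0.20) and TV (-0.31). Other lists changed sign between routes with a median inside the random range in at least 1 of the 2, such as basophil (0.63 in FV, -0.17 in TV), prostaglandin (0.12 in FV, -0.73 in TV) and dendritic cell genes (0.13 in FV, -0.46 in RP).

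The neutrophil and erythroid medians with ibuprofen lay above 0 in RP and below 0 in TV, and the platelet medians below 0 in both, with RP above TV. A candidate explanation is that the erythroid share moved the scaling of the counts. Taken gene by gene, the median difference between RP and TV was 1.38 for neutrophil and 0.71 for platelet genes, a measure apart from the difference of medians above. With the erythroid list left out it was 1.34 and 0.68, so leaving those genes out hardly moved the scaling between these pairs. Random lists then gave -0.26 to 0.23 and -0.10 to 0.33. A change of scaling moves markers and random lists alike, so lying outside that range was fixed in advance and does not bear on the explanation. Differing shares of neutrophils and platelets in each pair, from handling or from the response to collection, stay open and were not tested. A difference of the ibuprofen effect between routes also stays open, since with 1 pair per route it cannot be separated from differences between single libraries.

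FV without, FV with and TV without ibuprofen stood apart from Non by higher neutrophil and platelet genes. A lower lymphocyte share would raise all other cell types alike, but the neutrophil and platelet medians exceeded the nonclassical monocyte median by at least 0.79, with a lowest bootstrap bound of 0.372. That gap depended on the reference list. Classical monocyte medians, given above, lay nearer to the neutrophil and platelet medians in each of these libraries, though below them. The bootstrap drew genes, which vary together, so its bound leaves out differences between libraries. This test therefore cannot decide on the lymphocyte share. GC content and transcript length may act too, but after their trend was removed the lowest of the 6 medians was still 0.79, at percentile 100 of matched random lists. Rn7sk and Rn7s1, which have no poly(A) tail, had a median of 0.55 over the 3 libraries and were below Non in FV without ibuprofen, but carry-through of such RNA would not raise polyadenylated transcripts, so this test does not bear on the pattern. A lower lymphocyte share, collection itself, and the share of neutrophils and platelets kept when PBMCs were separated stay open.

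Saa3 and Chil3 were lower with ibuprofen in each of the 3 routes. Reads shared with other family members are a candidate explanation, but the summed counts of each family were also lower in all 3 routes. The least negative log2 ratio was -1.01, which argues against a shift of reads between counted members. The sums were mostly the genes themselves, as in FV without ibuprofen, where Saa3 held 14356 of 14365 Saa counts. Reads left uncounted would not show in these sums. A smaller share of neutrophils and classical monocytes is another candidate. Of 6 gene and route values, 4 lay below the lowest 2.5% of the 48 marker genes. Saa3 in FV and TV and Chil3 in RP lay below all 48 and at least 1.18 below that lowest 2.5%. These 3 values were set apart after they were seen, so they cannot decide whether that share was the whole cause. For Chil3 in FV and TV, inside the range of the markers, and for Saa3 in RP, below it on 53 and 8 family counts, that share cannot be told apart, with 1 of these 3 values below the lowest 2.5%. Tissue from the collection site was not weighed for these genes, and the filter did not show it to be absent. An effect of ibuprofen on these genes also stays open and is a hypothesis.

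The 6 collected libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes passing with edgeR, the real split and the highest of the others both gave 0, so 10 of 10 splits gave as many, while the real split had 1244 genes at an unadjusted p under 0.05 and DESeq2 called 110. For gene lists, the real split gave 18 and the highest of the others 18, so 3 of 10 splits gave as many. With a route term, splits that part only 1 route form pairs of the same comparison with the sign turned, so the 10 splits hold 7 distinct comparisons. The other 2 with 18 lists are such a pair and compare only the TV pair of libraries, with 2024 genes at an unadjusted p under 0.05, which points to the TV pair as a structure of these libraries. Among the 4 splits that part every route, the other 3 gave 10, 17 and 10 lists.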

How the results depend on the processing

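No test in this part was chosen after the result was seen. Alternative values of the tested lists numbered 1570. Under other settings 667 were the same in direction and call, 162 weaker, 23 stronger and 2 reversed, and with 1 library left out 574 were the same, 57 weaker, 80 stronger and 5 reversed. Of 70 list calls, 34 held without each library, 54 in every other setting that kept the preset correlation, and 32 in both. None held with an estimated correlation or with fry, where 0 lists passed in each of the 5 comparisons. Among named genes, 656 of 737 alternative values were the same and 81 passed where the reported value had not. Of 639 list medians between pairs of libraries 622 were the same and 17 moved, and all 71 list means with ibuprofen were the same.

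The number of genes passing depended on the tool. DESeq2 called 110 genes for ibuprofen, 1076 for RP minus FV, 318 for TV minus FV, 189 for TV minus RP and 17 against Non, where edgeR called 0. Limma-voom called 1, 48, 7, 0 and 1 in the same order, and the legacy form of the edgeR test called 1 gene against Non. With the erythroid list left out, edgeR called 18 genes for RP minus FV. The cause was not tested.

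Reversed list means were those of regulatory T cells with ibuprofen and no filter (-0.065) and of basophil, mast cell and eosinophil genes against Non at a mean of at least 5 CPM (0.20), where fewer genes of the list were measured. Without 1 library, erythroid genes with ibuprofen ranged from -0.47 to 0.11, interferon response genes in TV minus FV from -0.25 to 0.54, and immediate-early genes in TV minus RP from -0.39 to 0.034. Leaving out 1 library gave 0 to 8 genes for ibuprofen, 0 to 676 for RP minus FV, 0 to 14 for TV minus FV, 0 to 32 for TV minus RP and 0 to 3 against Non. The number of lists passing against Non ranged from 9 to 17. The lone library then left in a route was assumed to vary like the others.

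Genes at least 2-fold apart were counted at a mean of at least 10 CPM. At a mean of at least 1 CPM, which admits more genes, they numbered 1126 and 822 in FV without and with ibuprofen against Non, 164 and 166 in RP, 1466 and 168 in TV, and 387, 263 and 1161 for ibuprofen within FV, RP and TV. With the erythroid list left out the library sizes shrink and more genes reach 10 CPM. The counts were then 725 in FV without ibuprofen, 59 and 50 in RP without and with ibuprofen, 60 in TV with ibuprofen, and 200, 100 and 663 for ibuprofen within FV, RP and TV. On the TPM scale, with fewer genes above the limit, they were 16 in TV with ibuprofen, 100 for ibuprofen within RP and 206 within TV. The library with ibuprofen was nearer to Non in each route in all 6 settings of the distance. Depth limited precision at 10 CPM to counting error of -10.5% to 11.4% in the library with the smallest effective size, and lower levels are less precise.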

Other observations

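The genes in this part were chosen only after their values were seen, and no test was run on them. The median log2 fold of the 2 mitochondrial ribosomal RNA genes against Non was 1.54 and 1.19 in FV without and with ibuprofen, 0.42 and 0.07 in RP, and 2.02 and 0.83 in TV, while that of 9 mitochondrial mRNA genes was 0.21 and -0.30, 0.08 and 0.05, and 0.32 and 0.09. The median of 5 histone genes, Hist1h4n among them, was 1.00 and 1.68 in FV, 0.09 and -0.27 in RP, and 2.11 and 0.63 in TV. Pcp4l1 stood at 1.14 CPM in Non, 24.2 and 60.0 CPM in FV without and with ibuprofen, 1.79 and 24.9 CPM in RP, and 107 and 39.1 CPM in TV. Aak1 stood at 17.7 CPM in Non and between 31.9 and 56.1 CPM in the 6 collected libraries. Adamdec1 stood at 80.3 CPM in RP without ibuprofen and at most 16.3 CPM elsewhere. Ccdc6 stood at 4.28 CPM in TV without ibuprofen and at least 17.6 CPM elsewhere. Fkbp5, a glucocorticoid response gene, stood at 51.6 CPM in FV without ibuprofen and at most 19.1 CPM elsewhere. Hbq1a stood at 7.18 CPM in FV and 15.0 CPM in RP without ibuprofen and at least 78.2 CPM elsewhere, while its copy Hbq1b stood between 82.6 and 226 CPM in all 7 libraries.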
